A study of Homo sapiens with 24 samples.

How the data were processed

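RNA was sequenced from Nalm6 and Sem, established cell lines of B cell precursor acute lymphoblastic leukaemia; Sem carries a rearranged KMT2A gene. Cells of each line were left untreated or treated for 24 h with 10 µM ibrutinib, with asparaginase, or with both, which gave 8 groups of 3 libraries. The asparaginase dose was 1 IU/ml in the study design and sample characteristics and 0.5 IU/ml in the treatment protocol text, and the files do not settle which was used. The time of harvest of the untreated cells was not stated. The authors isolated RNA with RNeasy columns, prepared libraries with the NEBNext Ultra RNA kit and described the samples as triplicates; separate cultures were not described, so every p-value here measures only the spread between these libraries, which may be technical. Whether the libraries were stranded was not stated, so genes that overlap on opposite strands or have near-identical copies (HSPA1A and HSPA1B, HSPE1, NME1, MT1G, histones, HLA genes, ribosomal proteins and IGLL1) may share reads.

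The deposited unit was FPKM per gene, which the authors made with fastp, STAR and featureCounts (versions not given) on human build GRCh38, for 58735 genes in each of 24 libraries. All 299165 deposited values of 1 or more (21.2% of 1409640 cells) had lost their decimal point and held digits split by more than 1 dot. The 206596 values between 0 and 1 were intact. Each intact value times the gene length was a whole multiple of one step per library (largest deviation 9.1e-13 reads), so whole read counts could be recovered, and only the power of 10 of a damaged value was ambiguous. For each gene and line, the powers that gave whole reads in all 12 libraries were scored together, with Student t priors of 5 degrees of freedom on the log10 scale. The prior scales were 0.07 for replicate spread beyond counting error, 0.1 for the effect of ibrutinib, 0.13 for that of asparaginase and 0.08 for the interaction. These settings were reached after 4 versions, judged on simulated damage, on the share of restored counts that were multiples of 10 and on example genes, and the kinds of simulated changed genes were altered in the last version; the values of some drug-responsive genes had been seen by then, but no comparison had been tested. Of the restored values, 878 had a posterior under 0.99, and 461 of 15116 expressed genes held one. Among restored counts of 100 or more, 10.02% were multiples of 10, where 10% is expected of correct counts. When 298503 simulated values were damaged and restored, 99.941% came back correct. No gene among 40 simulated per fold that changed 2-, 4-, 8- or 16-fold with 1 drug, and equally in the combination, was restored wrongly. Among genes changed in the combination alone, 1 of 10 at 8-fold and 1 of 10 at 16-fold was. Genes changed by 1 drug and not in the combination were not simulated. The simulated counts were drawn around the restored group means, so a whole group restored at a wrong power of 10 could not show.

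Recovered reads assigned to genes numbered 15 to 18.1 M per library (median 16.2 M). The deposited FPKM also held a scaling factor per library of 0.919 to 1.093, by a method that was not stated. At the median library, 1 read in a gene of 1 kb stood for 0.0601 FPKM, which limits the precision of low values. All gene identifiers, starts and ends matched GENCODE 29 on GRCh38, and 58676 genes had a transcript sequence for GC content.

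Genes with FPKM of at least 1 in at least 3 libraries were tested by limma-trend on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment over the genes tested in a comparison; a gene was called at an adjusted p under 0.05. Within each line, 12 libraries were fitted with 8 residual degrees of freedom and 6 comparisons were made: each drug and the combination against untreated, the combination against each drug, and the interaction, which is the change with the combination minus the sum of the changes with the single drugs. All 24 libraries were fitted with 16 residual degrees of freedom for the differences between the lines (Sem minus Nalm6) in each effect and at baseline. A log2 change of FPKM + 1 understates the fold at low FPKM. Replicate numbers were not taken to pair the samples, and no pairing was stated. On simulated data, limma called 96% to 98% of genes changed 2-fold and 8 to 13 unchanged genes among 12919 to 13153 genes tested. At 1.25-fold it called 32% in Nalm6 and 56% to 58% in Sem, and at 1.5-fold 78% to 80% and 88%. Small simulated changes were thus missed more often in Nalm6, which limits the comparison of called counts between the lines. There, all genes of a line had the same spread beyond counting, the median of highly expressed genes. No simulated library had a trend on GC content or length, unlike the real ones, so these figures may not carry over.

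Before the data were examined, 34 gene lists were fixed, covering the amino acid response, lipid synthesis, growth and division, stress, B cell signalling, leukaemia genes and markers of other cell types. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. Called members were counted with adjustment over all genes and also adjusted over the list alone. On simulated data, camera called a shifted list and 0 of 29 unshifted ones. The simulated genes varied independently, so this does not show how often camera errs where members of a list are correlated.

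The named genes also followed a rule fixed then. They were protein-coding, and Y-linked genes, XIST and immunoglobulin and T cell receptor segments were left out. For a drug or the combination against untreated, the rule took the 8 highest and 8 lowest log2 changes among called genes whose groups of 3 did not overlap (10% of unchanged genes would by chance) and whose higher group averaged at least 5 FPKM. It took 5 per side for the combination against a single drug and for interactions, and 3 per side for differences between lines; interactions and line differences had no rule on overlap. Up to 4 members per list with the lowest p could be named, and BTK, ASNS, ATF4, DDIT3, CHAC1, TRIB3 and MYC were named whatever their values. Other named genes are said to be chosen after their values were seen.

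The alternatives planned were a pseudocount of 0.1, no filter, a filter at FPKM 5, rescaling to TPM, median-ratio scaling, quantile normalization, replicate number as a block, no variance trend, protein-coding genes alone, voom weights on recovered reads, both lines in 1 fit and leaving out each library. Chosen after seeing the data were leaving out genes with an uncertain restored value, leaving out 5 libraries that stood apart, and a spline correction (4 degrees of freedom) of each library for GC content and length. TPM rescaling moved the median log2 change of all genes by more than 0.1 in 4 comparisons: by 0.19, 0.21 and 0.13 in Nalm6 for asparaginase, the combination, and the combination against ibrutinib, and by 0.11 in Sem for the combination; a filter at FPKM 5 moved it by -0.11 in Nalm6 for the combination. The alternatives for single genes covered the genes picked by the rule, the 7 always given and the called ones among up to 4 members picked per called list, a scope narrowed after reversed results were seen. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. Raw reads were not used here.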

Results

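Gene expression was measured by RNA sequencing in 24 libraries, 3 for each of 4 treatments in Nalm6 and in Sem. The fewest reads assigned to genes were 15 M and the most 18.1 M. Between 11874 and 12735 genes reached 1 FPKM in a Nalm6 library and between 12276 and 12850 in a Sem library. Mitochondrial transcripts took 3.58% to 3.91% of reads in untreated and ibrutinib libraries of Nalm6, 4.3% to 4.81% in its asparaginase and combination libraries, and 2.35% to 2.81% in Sem. Libraries of a group correlated at r of 0.982 to 0.9895 in Nalm6 and 0.9857 to 0.9879 in Sem, across genes, which are not independent replicates. Libraries of different lines correlated at 0.79 to 0.839. Within its group, 1 library stood apart among Nalm6 untreated (number 2), asparaginase (1) and combination (1) and among Sem untreated (2) and ibrutinib (2). The trend of expression on GC content was 0.039, -0.092 and 0.014 log2 units per 10 points of GC in the untreated Nalm6 libraries and -0.129, 0.068 and 0.086 in the combination ones, while all Sem libraries lay between -0.039 and 0.061. Of the markers of other cell types, 2 of 15 myeloid, 3 of 16 T and NK cell, 3 of 10 plasma and mature B cell and 1 of 12 erythroid and stromal markers were tested in Nalm6, too few for a list test. In Sem 3, 3, 2 and 2 were.

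**Figure D1:**
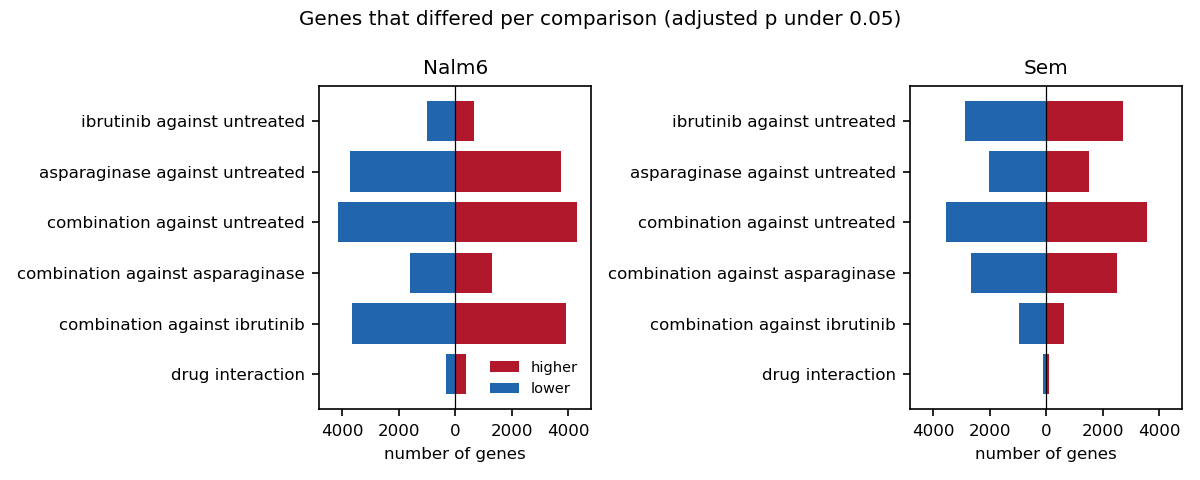
Number of genes called higher (right, red) and lower (left, blue) at a limma adjusted p under 0.05 in each comparison within Nalm6 and Sem. Asparaginase gave 7438 called genes in Nalm6 and 3542 in Sem, and ibrutinib 1650 and 5563.

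**Figure D2:**
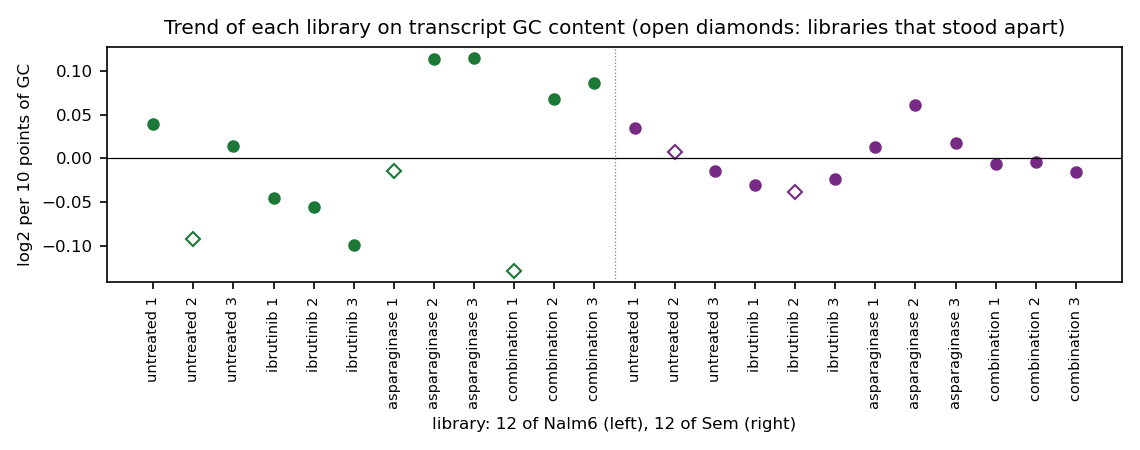
Slope of each library's expression on the GC content of transcripts, relative to the mean of its line, in log2 units per 10 points of GC; open diamonds are the 5 libraries that stood apart. The Nalm6 combination libraries range from -0.129 to 0.086, and all Sem libraries lie between -0.039 and 0.061.

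The first comparison asked what ibrutinib, an inhibitor of the B cell kinase BTK, did to RNA levels in Nalm6. Members of the ATF4 stress list were higher than in untreated cells. Genes of cholesterol synthesis and of the list of MYC and MYC-induced genes were lower. DDIT3 (ENSG00000175197, GRCh38 chromosome 12, 57516588 to 57521737, minus strand), a transcription factor of the stress response, rose from 10.1 ± 1.04 to 19.1 ± 1.12 FPKM (SD, n = 3, log2 change 0.86 ± 0.085, SE, limma adjusted p = 0.00023). PHYH (ENSG00000107537, chromosome 10, 13277796 to 13302412, minus strand), a peroxisomal enzyme that breaks down phytanic acid, rose from 11.8 ± 0.537 to 30.7 ± 1.13 FPKM (1.31 ± 0.056, adjusted p = 1.5e-06). PTPN6 (ENSG00000111679, chromosome 12, 6946468 to 6961316, plus strand), a phosphatase that restrains B cell receptor signalling, fell from 24.2 ± 1.34 to 8.05 ± 0.0223 FPKM (-1.47 ± 0.071, adjusted p = 1.5e-06).

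Among other genes the rule picked in Nalm6 with ibrutinib, RAG1, part of the recombinase that assembles immunoglobulin genes, rose from 75.6 ± 3.07 to 149 ± 5.16 FPKM, and TP53INP1, a p53 target, from 3.17 ± 0.163 to 7.5 ± 0.44. HRK, a member of the BCL2 family that promotes cell death, rose by 0.88 on the log2 scale and NQO1, a quinone reductase, by 0.96. The kinase LCK fell from 15.1 ± 1.71 to 7.08 ± 0.287 FPKM and S100A4 from 31.9 ± 1.8 to 16.1 ± 0.478. The rule required all 3 treated libraries of each such gene to lie on one side of all 3 untreated ones, so this separation adds no support. Of the 18 tested members of the ATF4 list (regulators and targets of the amino acid and stress response), 15 rose and 0 fell, and 17 and 0 adjusted over the list alone (mean log2 change 0.397, camera adjusted p = 2.78e-14), with KLHL24 at 0.72 and CHAC1 at 0.9. In the cholesterol synthesis and uptake list 1 rose and 16 of 22 fell (2 and 20 adjusted over the list alone, mean -0.41, camera adjusted p = 1.13e-13), among them HMGCS1 (-0.95), INSIG1 (-0.79) and FDFT1 (-0.72). In the MYC list 15 of 33 fell and 0 rose (20 and 0 over the list alone, mean -0.23, camera adjusted p = 1.62e-10), with LDHA at -0.54. Calls for these 3 lists held with an estimated correlation.

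The mitosis list (17 of 30 fell, 0 rose, mean -0.25, camera adjusted p = 2.32e-12) gave an adjusted p = 0.0502 with an estimated correlation. AURKA changed by -0.47 and CDC20 by -0.53. Lower by camera with the preset correlation were also glycolysis (10 of 20 members fell), fatty acid synthesis (7 of 11), the nuclear encoded respiratory chain (8 of 36) and DNA replication (7 of 35), and amino acid transport was higher (4 of 14 rose, SLC7A11 by 0.6). With an estimated correlation their adjusted p lay from 0.0558 to 0.313. The ER chaperone list (1 rose, 6 of 20 fell, adjusted p = 0.0297) had a mean of -0.08 that turned to 0.002 under quantile normalization, and its call was lost without untreated 2 (adjusted p = 0.0621) or ibrutinib 2 (0.0525). The heat shock call (4 of 14 fell, adjusted p = 0.0324) was lost without untreated 2 (0.114), ibrutinib 1 (0.0665) or ibrutinib 2 (0.0731). With an estimated correlation these gave adjusted p = 0.0973 and 0.427. The other 19 lists did not pass, from MHC class II (adjusted p = 0.0595) to the interferon response (0.884). Amino acid synthesis had a mean of -0.04 and a median of 0.08. The mean was positive under TPM and quantile scaling, and under the latter the list was called higher (camera adjusted p = 0.0265). BTK (log2 change 0.13), ASNS (0.1), ATF4 (0.11) and MYC (-0.19) did not pass. ASNS itself averaged 0.542 ± 0.0505 FPKM in untreated cells.

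By limma, 1650 of 13237 genes passed in Nalm6 with ibrutinib (660 higher, 990 lower, 3714 at an unadjusted p under 0.05), and 14 rose and 8 fell at least 2-fold. The count and its split moved with the processing: 972 higher and 390 lower under TPM rescaling, 478 and 379 under quantile normalization, 1056 called with no filter, 2507 with both lines in 1 fit, 3325 without the libraries that stood apart and 2672 after the GC and length correction. Leaving out untreated 1 gave 955, untreated 3 gave 703, and ibrutinib 1, 2 and 3 gave 836, 758 and 957. The call of TRIB3 (0.46 ± 0.11, adjusted p = 0.021) was lost without untreated 2 (0.0567), untreated 3 (0.0517), ibrutinib 1 (0.0737) or ibrutinib 2 (0.0645). ASS1 had the lowest fitted change (-1.89), but the decimal place of its 3 untreated values was uncertain, and values 10 times lower would turn its direction.

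The second comparison asked what asparaginase, an enzyme that removes extracellular asparagine, did in Nalm6. Stress genes of the ATF4 list and MHC class II genes were higher, while chaperones, DNA replication, MYC-induced and cholesterol genes were lower. DDIT3 rose from 10.1 ± 1.04 to 63.3 ± 5.92 FPKM (2.54 ± 0.085, limma adjusted p = 5.1e-09). TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559, plus strand), a pseudokinase induced by DDIT3 and ATF4, rose from 23 ± 1.91 to 174 ± 18.1 FPKM (2.86 ± 0.11, adjusted p = 1.1e-08). HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330, minus strand), the main chaperone of the endoplasmic reticulum, fell from 161 ± 5.21 to 42.5 ± 0.953 FPKM (-1.9 ± 0.039, adjusted p = 3.5e-10), and HSPA8, the constitutive cytosolic one, from 660 ± 25.5 to 180 ± 6.73. HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512, minus strand), an early enzyme of cholesterol synthesis, fell from 79.7 ± 5.24 to 18.6 ± 0.799 FPKM (-2.04).

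All 18 tested members of the ATF4 list rose in Nalm6 with asparaginase (mean log2 change 1.37, camera adjusted p = 8.97e-13), among them PPP1R15A, which lifts the block on translation, at 2.5 and CHAC1, a glutathione-degrading enzyme, at 1.74. WARS, a tRNA synthetase, rose from 15 ± 0.67 to 78.1 ± 0.791 FPKM, but of its list of 20 synthetases 8 rose and 10 fell (mean 0.02, median -0.15, adjusted p = 0.881). All 9 MHC class II genes rose (mean 0.93, adjusted p = 2.19e-06), HLA-DMB by 1.49. DNA replication (33 of 35 fell, mean -0.75, camera adjusted p = 1.56e-15), the MYC list (32 of 33, 33 adjusted over the list alone, mean -0.82, camera adjusted p = 8.13e-15), heat shock proteins (14 of 14, mean -1.47, camera adjusted p = 6.63e-11) and cholesterol (20 of 22, with 2 higher, mean -0.75, camera adjusted p = 2.18e-08) were lower, and no member of the first 3 rose. Examples were RRM1, a subunit of ribonucleotide reductase (-1.42), TFRC, the transferrin receptor (-1.79), and LDHA (-1.59). In the ER chaperone list 15 of 20 fell and 5 rose (mean -0.52, adjusted p = 0.000486), and EDEM1, which sends misfolded proteins to degradation, rose by 1.66. All 7 of these lists held with an estimated correlation. In the pre-B cell receptor list 9 rose and 6 fell (adjusted p = 0.397): IGLL1, a surrogate light chain, fell from 1030 ± 69.2 to 371 ± 18.2 FPKM.

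The respiratory chain (33 of 36 fell), fatty acid synthesis (11 of 11), glycolysis (15 of 20, 1 rose), mitosis (21 of 30, 3 rose) and NRF2 targets (10 of 14, 2 rose) were lower, and amino acid transport (9 of 14 rose, 1 fell), p53 targets (9 of 22, 4 fell), B lineage transcription factors (9 of 19, 4 fell) and autophagy genes (9 of 23, 1 fell) higher, by camera with the preset correlation. Their adjusted p lay from 0.0507 to 0.41 with an estimated one. SCD, the stearoyl-CoA desaturase, changed by -1.72, SLC3A2, an amino acid carrier, by 1.24 and the autophagy gene MAP1LC3B by 1.68. Calls were lost without asparaginase 2 for p53 targets (adjusted p = 0.0519), without untreated 2 for B lineage factors (0.0568), and without untreated 2 (0.101), asparaginase 2 (0.0677) or asparaginase 3 (0.0607) for autophagy. Ribosomal proteins were lower (28 of 77 fell, 3 rose, mean -0.16, adjusted p = 0.00668, and adjusted p = 0.53 with an estimated correlation), but they were called higher under quantile normalization (35 rose, 7 fell, mean 0.15, camera adjusted p = 0.00049). Amino acid synthesis did not pass (9 of 15 rose, 4 fell, mean 0.21, camera adjusted p = 0.143). It was called higher under quantile normalization (mean 0.364, camera adjusted p = 0.00265) and by fry (adjusted p = 7.75e-06). Another 12 lists did not pass, from FOXO targets (adjusted p = 0.0963) to the interferon response (0.956). Among them, genes of the BCL2 family, which set the threshold for cell death, went both ways (7 rose, 6 fell, camera adjusted p = 0.76), with BMF at 1.47 and BID at -0.92. ASNS, asparagine synthetase, rose from 0.542 ± 0.0505 to 1.57 ± 0.138 FPKM (0.73), ATF4 by 0.25, and MYC fell from 334 ± 22.3 to 225 ± 19.1 (-0.57). BTK (0.04) did not pass. By limma, 7438 of 13237 genes passed (3731 higher, 3707 lower), and 5713 higher and 2547 lower after TPM rescaling. Library trends on transcript length followed the treatment, from -0.119 to -0.045 log2 units per doubling of length in untreated and 0.051 to 0.083 in asparaginase libraries. The GC and length correction kept 94.3% of the calls.

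**Figure D3:**
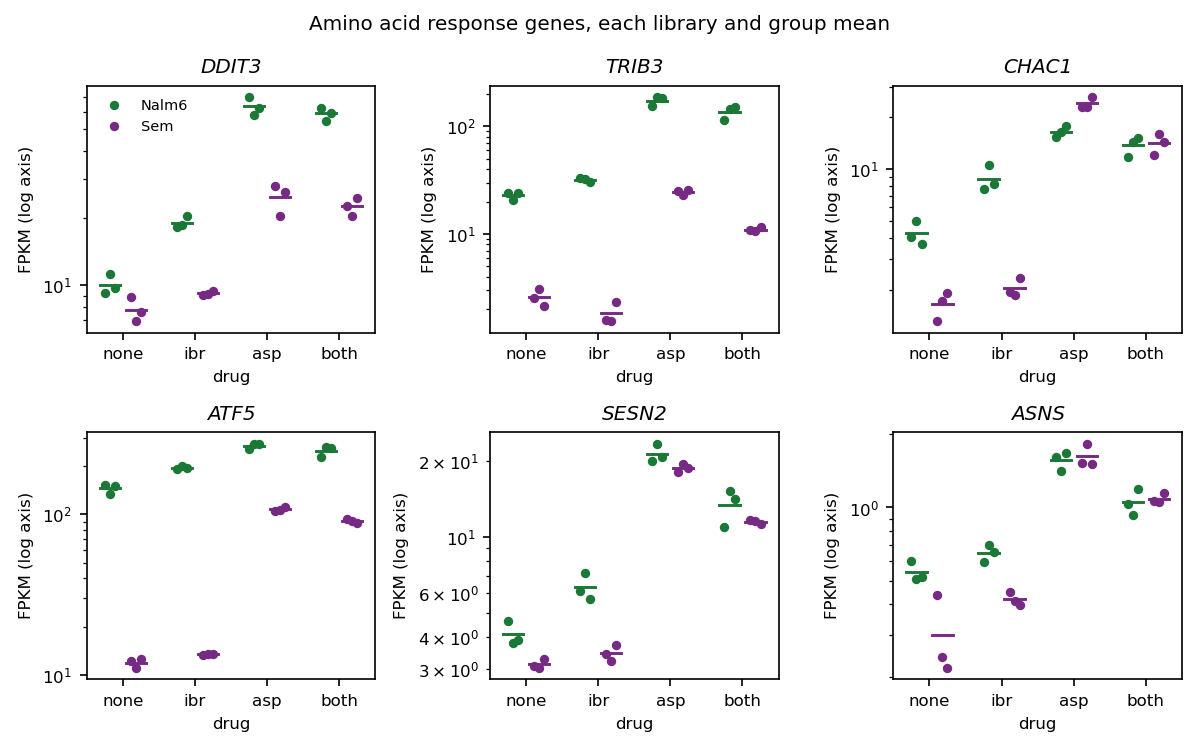
FPKM (log axis) of DDIT3, TRIB3, CHAC1, ATF5, SESN2 and ASNS in each library (points) and the group mean (line) for no drug, ibrutinib (ibr), asparaginase (asp) and both, in Nalm6 (green) and Sem (purple). With asparaginase, TRIB3 averages 174 FPKM in Nalm6 and 24.4 in Sem, against 23 and 2.6 without drug.

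The third comparison asked what both drugs together did in Nalm6. DNA replication and MYC list genes fell, and FOXO targets, which mark resting cells, rose. MYC (chromosome 8, 127735434 to 127741434, plus strand) fell from 334 ± 22.3 to 147 ± 22.9 FPKM (-1.19 ± 0.11, limma adjusted p = 2.3e-06). TP53INP1 rose from 3.17 ± 0.163 to 26.9 ± 0.149 FPKM (2.74 ± 0.05, adjusted p = 2.2e-10), and BMF, a BCL2 family member that promotes cell death, from 0.442 ± 0.0278 to 6.68 ± 0.279. TSPAN8, a tetraspanin, rose from 0.193 ± 0.0416 to 11.3 ± 1.34 FPKM. SCD fell from 98.1 ± 6.02 to 19.8 ± 0.579 FPKM and NME1, a nucleotide kinase, from 28.8 ± 4.02 to 4.86 ± 0.571.

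All 35 DNA replication genes (mean log2 change -1.13, camera adjusted p = 3.54e-17) and all 33 of the MYC list (mean -1.29, camera adjusted p = 8.24e-17) fell in Nalm6 with the combination, with MCM4 at -1.63 and LDHA at -2.04. All 18 ATF4 list members rose (mean 1.26, camera adjusted p = 1.8e-09), as did 9 of 9 MHC class II genes (mean 1.05, camera adjusted p = 1e-05), 13 of 17 FOXO targets (2 fell, mean 0.68, camera adjusted p = 0.00048), with CCNG2 at 2.21 and BTG1 at 1.69, and 15 of 22 p53 targets (4 fell, mean 0.45, camera adjusted p = 0.00336), with BTG2 at 2.08. In the cholesterol list 19 of 22 fell and 2 rose (mean -0.87, camera adjusted p = 2.16e-07). These 7 held with an estimated correlation. Heat shock proteins, fatty acid synthesis, glycolysis, the respiratory chain, ER chaperones and tRNA synthetases were lower, and B lineage factors, autophagy genes and histones higher, with adjusted p of 0.0513 to 0.277 with an estimated correlation. The histone call was lost without combination 1 (0.0547), 2 (0.0811) or 3 (0.0537). Mitosis (16 of 30 fell, 4 rose, mean -0.21, camera adjusted p = 0.0307) and ribosomal proteins (33 of 77 fell, 2 rose, mean -0.21) turned direction under quantile normalization and gave adjusted p = 0.433 and 0.436 with an estimated correlation. Under quantile normalization ribosomal proteins were called higher (30 rose, 14 fell, camera adjusted p = 0.0498). The mitosis call was lost without untreated 2 (0.0552), combination 2 (0.0586) or combination 3 (0.0522). Amino acid synthesis did not pass (4 rose, 6 of 15 fell, mean -0.19, camera adjusted p = 0.562), nor did 11 more lists, from amino acid transport (0.0856) to mitochondrial messenger RNAs (0.913). In the pre-B cell receptor list 9 rose and 7 fell, with CD79A at 2.03 and IGLL1 at -2.06. DDIT3 (2.44), TRIB3 (2.52), CHAC1 (1.49), ASNS (0.41) and BTK (0.24) rose. The call of ATF4 (0.12) was lost without untreated 1 (0.105), untreated 2 (0.0674) or combination 2 (0.092). By limma, 8429 of 13237 genes passed (4290 higher, 4139 lower, 6622 and 3127 after TPM rescaling). The trend on transcript length was 0.044 to 0.103 in the combination libraries, and 94.9% of the calls were kept with the GC and length correction.

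The next pair of comparisons asked what each drug added to the other in Nalm6. Adding ibrutinib to asparaginase raised RAG1 (log2 change 1.46), GZMA (2.14), the lymphotoxin gene LTB (1.82) and PRKCZ, an atypical protein kinase C (1.73 ± 0.06, limma adjusted p = 7e-08), and lowered MYC (-0.62 ± 0.11). MYC list genes (29 of 33 fell, 31 adjusted over the list alone, mean -0.47, camera adjusted p = 3.7e-20), DNA replication (31 of 35, mean -0.38), tRNA synthetases (14 of 20, mean -0.29) and amino acid synthesis (12 of 15 fell, 1 rose, mean -0.4) were lower, and these 4 held with an estimated correlation. The ATF4 list (8 fell, 3 of 18 rose, mean -0.11, camera adjusted p = 0.0216) gave adjusted p = 0.0945 with an estimated correlation, and 14 more called lists gave 0.051 to 0.403. Of these the interferon call was lost without asparaginase 1 (0.0542) or combination 1 (0.0622). Calls of ASNS (-0.32), ATF4 (-0.14) and TRIB3 (-0.34) were each lost in at least 4 of 6 fits without 1 library (adjusted p up to 0.0998, 0.125 and 0.143). DDIT3 (-0.1) and CHAC1 (-0.25) did not pass. BTK rose by 0.2. In all 2888 genes passed (1299 higher, 1589 lower). Adding asparaginase to ibrutinib raised PPP1R15A (2.43 ± 0.075, adjusted p = 3.2e-09), DDIT3 (1.58), TRIB3 (2.06) and CHAC1 (0.59) and lowered the nucleoside transporter SLC29A1 (-1.88), ID3 (-1.87) and MYC (-1.01). DNA replication (34 of 35 fell) and the MYC list (33 of 33) were lower, and the ATF4 list (16 of 18 rose, mean 0.86, camera adjusted p = 1.18e-07) and MHC class II (9 of 9) higher. These held with an estimated correlation, as did 6 more of 17 called lists. The mean of the ribosomal proteins (-0.22) turned to positive under quantile normalization, and its adjusted p was 0.394 with an estimated correlation. ATF4 (0.01) did not pass. The calls of ASNS (0.31) without combination 3 (0.0552) and of BTK (0.1) without any 1 of the 6 libraries (up to 0.152) were lost. By limma, 7562 genes passed (3902 higher, 3660 lower, 5389 and 3006 after TPM rescaling).

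The interaction asked whether the combination in Nalm6 differed from the sum of the single drugs. ATF4 list genes lay below that sum (14 of 18 lower, 0 higher, 15 and 2 adjusted over the list alone, mean log2 interaction -0.51, camera adjusted p = 6.48e-14). Examples were DDIT3 (-0.96 ± 0.12, limma adjusted p = 0.0015), SESN2, an inhibitor of mTORC1 signalling (-1.17), and CHAC1 (-1.15). Outside it, PCK2, mitochondrial PEPCK (-1.25 ± 0.099, adjusted p = 0.00011), also lay below. Amino acid synthesis (9 of 15 lower, 2 higher, mean -0.36), amino acid transport (7 of 14, mean -0.38), tRNA synthetases (9 of 20, mean -0.29), DNA replication (12 of 35, 1 higher, mean -0.29) and the MYC list (7 of 33, mean -0.24) were lower. Mitosis genes lay above the sum (15 of 30 higher, 0 lower, mean 0.4, camera adjusted p = 8.94e-18), AURKA and CDC20 each by 0.84. So did cholesterol (6 of 22 higher, 1 lower, mean 0.29, INSIG1 1.19), heat shock (7 of 14, mean 0.38), ER chaperones (6 of 20, 1 lower, mean 0.22, HSPA5 0.8), FOXO targets (4 of 17, 1 lower), p53 targets (5 of 22) and histones (1 of 6). PRKCZ (1.38 ± 0.086, adjusted p = 3.9e-05) and KLF2, a FOXO target of quiescent lymphocytes (1.6 ± 0.27, adjusted p = 0.0069), had the highest interactions of the picked genes. Those 13 lists held with an estimated correlation. Others were called with the preset one: B lineage factors, NRF2 targets and autophagy, with adjusted p of 0.0925 to 0.18 with an estimated correlation, and ribosomal proteins, respiratory chain, NF-kB and interferon genes, with 0.0853 to 0.616 and calls lost in at least 5 of 12 fits without 1 library (adjusted p up to 0.339). TRIB3 passed (-0.8). The call of ATF4 (-0.25) was lost in 9 of 12 such fits (adjusted p up to 0.0922). ASNS (-0.42), MYC (-0.44) and BTK (0.07) did not pass. By limma 736 genes passed (396 higher, 340 lower, 230 and 418 after TPM rescaling), 1364 with both lines in 1 fit, 1586 without the libraries that stood apart and 1647 after the GC and length correction. The count was 454 without untreated 3, 459, 430 and 463 without ibrutinib 1, 2 and 3, 456 and 442 without asparaginase 2 and 3, and 490 without combination 2.

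In Sem, ibrutinib was asked about in the same way. Most early activation genes of receptor signalling fell, with DUSP6, EGR1 and SPRY4 among those that ended under 1 FPKM, and the surrogate light chain gene IGLL1 rose. DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271, minus strand), a phosphatase induced by ERK signalling, fell from 5.91 ± 0.595 to 0.292 ± 0.109 FPKM (-2.42 ± 0.09, limma adjusted p = 4.5e-08). EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315, plus strand), an immediate early transcription factor, fell from 11.1 ± 3.03 to 0.431 ± 0.117 FPKM (-3.06 ± 0.23, adjusted p = 2.8e-06). 1 of its restored values, in asparaginase 1, was uncertain. KCNK3 (chromosome 2, 26692690 to 26733420, plus strand), a potassium channel gene, fell from 6.56 ± 0.386 to 0.066 ± 0.0225 FPKM, ITGB2, an integrin chain, from 10.1 ± 0.457 to 1.86 ± 0.0154, and ANPEP, an aminopeptidase, from 20.1 ± 0.723 to 5.49 ± 0.0858. IGLL1 (ENSG00000128322, chromosome 22, 23573125 to 23580308, minus strand) rose from 165 ± 5.82 to 322 ± 5.24 FPKM. NQO1 rose from 7.09 ± 0.659 to 18.7 ± 1.56 and KLHL24 from 6.51 ± 0.134 to 15.8 ± 0.261.

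Of 18 early activation genes of receptor signalling, 13 fell and 3 rose in Sem with ibrutinib, also adjusted over the list alone (mean log2 change -0.83, camera adjusted p = 1.31e-05), SPRY4 by -1.77 and ETV5 by -1.31. The MYC list (31 of 33 fell, 1 rose, mean -0.46, camera adjusted p = 2.18e-15), DNA replication (30 of 35, 1 rose, mean -0.28, camera adjusted p = 4.68e-11) and heat shock proteins (16 of 16, mean -0.42, camera adjusted p = 1.95e-10) fell too, although MYC rose by 0.14 ± 0.026 (adjusted p = 0.0013, and 0.189 with both lines in 1 fit). These 4 lists held with an estimated correlation. The respiratory chain (28 of 35 fell), glycolysis (15 of 21), tRNA synthetases (17 of 20), cholesterol (13 of 23, 3 rose), ER chaperones (14 of 20, 3 rose), MHC class II (6 of 10) and fatty acid synthesis (7 of 12) were lower, and B lineage factors (12 of 19 rose, 2 fell, BACH2 at 1.07) and FOXO targets (9 of 17 rose, 2 fell, SESN3 at 0.95) higher, with adjusted p of 0.0894 to 0.311 with an estimated correlation. The call of mitochondrial messenger RNAs (5 of 13 fell, adjusted p = 0.579 with an estimated correlation) was lost without untreated 2 (0.157) or ibrutinib 1 (0.11). The ATF4 list (6 rose, 3 of 18 fell, mean 0.12, camera adjusted p = 0.126), amino acid synthesis (2 rose, 7 of 14 fell, mean -0.07, positive under TPM and quantile scaling, camera adjusted p = 0.283) and the pre-B cell receptor list (8 rose, 5 of 20 fell, camera adjusted p = 0.514) were among the 16 that did not pass, from ribosomal proteins (0.0512) to the interferon response (0.834). The ATF4 list was called higher under TPM rescaling (mean 0.227, camera adjusted p = 0.0473) and by fry (adjusted p = 0.000845). BTK (-0.08, positive under TPM and quantile scaling), ASNS (0.13), ATF4 (0.03), DDIT3 (0.22) and CHAC1 (0.21) did not pass. The call of TRIB3 (-0.35) was lost in 4 of 6 fits without 1 library (adjusted p up to 0.0929). By limma, 5563 of 13417 genes passed (2711 higher, 2852 lower, 3985 and 2007 after TPM rescaling). Trends on transcript length were -0.104, -0.022 and -0.097 in untreated and 0.019 to 0.036 in ibrutinib libraries, and the GC and length correction kept 83.6% of the calls.

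**Figure D4:**
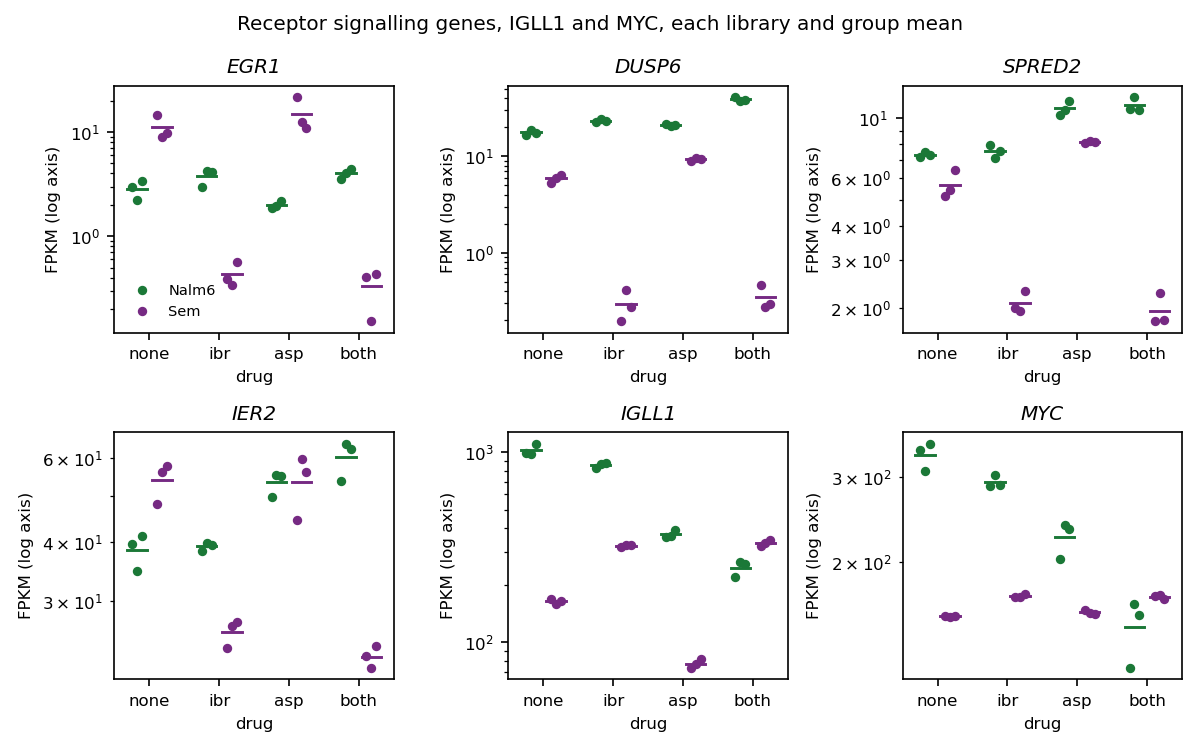
FPKM (log axis) of EGR1, DUSP6, SPRED2, IER2, IGLL1 and MYC in each library (points) and the group mean (line), in Nalm6 (green) and Sem (purple) with no drug, ibrutinib (ibr), asparaginase (asp) or both; IER2 was chosen for the plot after its values were seen. In Sem, DUSP6 averages 5.91 FPKM without drug and 0.292 with ibrutinib, while in Nalm6 it averages 17.7 and 23.4.

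Asparaginase in Sem raised most genes of the amino acid response and lowered mitosis and sterol genes. ATF5 (ENSG00000169136, chromosome 19, 49928702 to 49933935, plus strand), a transcription factor downstream of ATF4, rose from 11.9 ± 0.783 to 108 ± 3.45 FPKM (3.08 ± 0.045, limma adjusted p = 1.3e-11), CHAC1 (chromosome 15, 40952962 to 40956519, plus strand) from 1.65 ± 0.311 to 24 ± 1.79, and SLC7A11, the cystine carrier, from 0.717 ± 0.0683 to 8.06 ± 0.343. PSAT1, a serine synthesis enzyme, rose from 86.7 ± 4.85 to 312 ± 15.2 FPKM. PLK1, a mitotic kinase, fell from 30.6 ± 1.28 to 16.9 ± 0.484 FPKM (-0.82 ± 0.044, adjusted p = 2.9e-07), IGLL1 from 165 ± 5.82 to 77.2 ± 3.98 and VPREB1, its partner in the surrogate light chain, from 66.4 ± 4.66 to 37.4 ± 0.566.

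In the ATF4 list 16 of 18 rose and 1 fell in Sem with asparaginase (mean log2 change 1.4, camera adjusted p = 1.93e-22), with SESN2 at 2.26 and STC2 at 1.77. Amino acid transport (12 of 15 rose, 1 fell, mean 0.79, camera adjusted p = 3.06e-13, SLC6A9 2.47) and amino acid synthesis (11 of 14 rose, 2 fell, mean 0.75, camera adjusted p = 1.19e-10, GPT2 1.56) were higher. Mitosis (28 of 30 fell, all 30 adjusted over the list alone, mean -0.44, camera adjusted p = 1.29e-21), cholesterol (21 of 23, mean -0.41, camera adjusted p = 6.5e-17), heat shock (15 of 16, mean -0.39), DNA replication (26 of 35, mean -0.21), fatty acid synthesis (10 of 12, mean -0.33) and glycolysis (13 of 21, mean -0.3) were lower with 0 members higher. These 9 held with an estimated correlation. tRNA synthetases (12 of 20 rose, 4 fell, WARS 2.42), MHC class II (5 of 10 rose), early activation genes (5 of 18) and KMT2A-rearranged leukaemia genes (7 of 16, 2 fell) were higher and the MYC list (18 of 33 fell), respiratory chain (29 of 35) and mitochondrial messenger RNAs (5 of 13) lower, with adjusted p of 0.0536 to 0.374 with an estimated correlation. ER chaperones did not pass (4 rose, 6 of 20 fell, adjusted p = 0.8), nor did 13 more lists, from histones (0.118) to NF-kB targets (0.977). TRIB3 (2.83), DDIT3 (1.55), ASNS (1.02) and ATF4 (0.44) rose. BTK (-0.11) and MYC (0.03) did not pass. By limma, 3542 of 13417 genes passed (1522 higher, 2020 lower, 2632 and 1098 after TPM rescaling), and 85.2% of the calls were kept with the GC and length correction.

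The combination in Sem raised the ATF4 list and lowered early activation, mitosis and MYC list genes. ATF5 rose from 11.9 ± 0.783 to 91.1 ± 2.83 FPKM (2.83 ± 0.045, limma adjusted p = 3.3e-11), CHAC1 by 2.51, SLC7A11 by 2.04 and NQO1 by 1.68. DUSP6 fell from 5.91 ± 0.595 to 0.345 ± 0.107 FPKM (-2.36), KCNK3 by 2.84 on the log2 scale and EGR1 by 3.16. All 18 ATF4 list members rose (mean log2 change 1.12, camera adjusted p = 7.95e-12), 13 of 18 early activation genes fell and 4 rose (mean -0.86, camera adjusted p = 0.000131), 29 of 30 mitosis genes fell (mean -0.56, camera adjusted p = 1.06e-13, CDC20 -1.23), and so did 31 of 33 in the MYC list (1 rose, mean -0.67), 32 of 35 DNA replication genes (3 rose, mean -0.42) and 16 of 16 heat shock proteins (-0.67). These 6 held with an estimated correlation. Amino acid synthesis (10 of 14 rose, 2 fell, mean 0.37, camera adjusted p = 0.00329) gave adjusted p = 0.296 with an estimated correlation, and 9 more called lists 0.0626 to 0.615, of which ribosomal proteins (37 of 76 rose, 1 fell) had the last. Mitochondrial messenger RNAs were among them, with a call lost without untreated 2 (0.075), combination 1 (0.075) or combination 3 (0.0524). TRIB3 (1.74), DDIT3 (1.43), ASNS (0.69), ATF4 (0.3) and MYC (0.14) rose. BTK (-0.15, adjusted p = 0.0063) turned direction under quantile normalization. By limma, 7090 genes passed (3568 higher, 3522 lower, 4999 and 2740 after TPM rescaling), and the GC and length correction kept 89.6%.

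Adding ibrutinib to asparaginase in Sem raised IGLL1 from 77.2 ± 3.98 to 333 ± 11.3 FPKM (2.1 ± 0.044, limma adjusted p = 2.1e-10), VPREB3 (1.45) and the surface marker CD24 (1.32), and lowered DUSP6 (-2.94), AHRR (-2.33), KCNK3 (-3.42) and EGR1 (-3.53). The early activation list (13 of 18 fell, 2 rose, mean -1.01, camera adjusted p = 9.19e-07) and the MYC list (30 of 33, 1 rose, mean -0.48, camera adjusted p = 5.06e-17) held with an estimated correlation. The ATF4 list (10 of 18 fell, 3 rose, mean -0.28, camera adjusted p = 0.00143) and amino acid synthesis (13 of 14 fell, 1 rose, mean -0.37) gave adjusted p = 0.206 and 0.0786 with one, and 14 more called lists 0.0669 to 0.49. CHAC1 (-0.73) and TRIB3 (-1.08) fell and MYC rose by 0.11. ATF4 (-0.13), DDIT3 (-0.12) and BTK, whose direction turned under quantile normalization, did not pass, and the call of ASNS (-0.33) was lost without any 1 of the 6 libraries (up to 0.111). In all 5141 genes passed (2494 higher, 2647 lower). Adding asparaginase to ibrutinib raised ATF5 (2.67), CHAC1 (2.31), TRIB3 (2.1) and WARS (1.82) and lowered CCNB1, a mitotic cyclin, from 64.3 ± 1.44 to 34.6 ± 2.08 FPKM (-0.88 ± 0.046) and KIF20A (-0.82). All 30 mitosis genes fell (-0.5, adjusted p = 2.14e-36) and 16 of 18 of the ATF4 list rose (mean 0.999, camera adjusted p = 2.95e-28). These and 7 more of 15 called lists held with an estimated correlation, among them interferon genes (4 of 20 rose, 1 fell, mean 0.18). The BCL2 family call (5 of 13 rose, PMAIP1 by 0.48, adjusted p = 0.113 with an estimated correlation) was lost without combination 3 (0.0586). The other 5 called lists gave 0.0552 to 0.592 with an estimated correlation. DDIT3 (1.21), ASNS (0.56) and ATF4 (0.28) rose, and BTK (-0.06) and MYC (0, either sign under other settings) did not pass. By limma, 1624 genes passed (648 higher, 976 lower), and 1081, 1063, 1044 and 1053 without ibrutinib 2 and combination 1, 2 and 3.

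The interaction in Sem again placed the amino acid response below the sum of the single drugs. In the ATF4 list 8 of 18 were lower and 0 higher (13 and 1 adjusted over the list alone, mean log2 interaction -0.4, camera adjusted p = 8.9e-14), with SESN2 at -0.77 and CHAC1 at -0.94. Amino acid transport (9 of 15 lower, 0 higher, mean -0.34, SLC7A11 -0.92 ± 0.077, limma adjusted p = 0.0005) and amino acid synthesis (7 of 14, mean -0.31, GPT2 -0.67) lay below too, and cholesterol genes above (11 of 23 higher, 0 lower, mean 0.29, camera adjusted p = 7.15e-20, IDI1 0.45). These 4 held with an estimated correlation. IGLL1 lay above the sum (1.13 ± 0.062, adjusted p = 2.1e-05) and VPREB1 by 0.61. Their list (3 of 20 higher, adjusted p = 0.0177, and 0.194 with an estimated correlation) lost its call without untreated 2 (0.0672). Of 12 more lists called with the preset correlation, adjusted p lay from 0.0731 to 0.569 with an estimated one. The means of ribosomal proteins and mitochondrial messenger RNAs turned direction under quantile normalization and that of DNA replication under TPM rescaling, and calls were lost for mitosis in 5 of 12 fits without 1 library (up to 0.116) and for mitochondrial messenger RNAs without untreated 2 (0.0567). The call of TRIB3 (-0.73) was lost in 11 of 12 such fits (up to 0.114), and those of VPREB3 (0.69) and FUT7 (0.78) in 9 (up to 0.0924 and 0.0763). BTK (0.04), ASNS (-0.46), ATF4 (-0.16), DDIT3 (-0.34) and MYC (-0.03) did not pass. By limma, 207 of 13417 genes passed (102 higher, 105 lower, 65 and 290 after TPM rescaling, 93 and 167 after quantile normalization). The GC and length correction kept 83.6% of them. The count was 136 with no filter, 405 among protein-coding genes and 533 with voom weights. It was 115, 369 and 98 without untreated 1, 2 and 3, 92, 116 and 98 without ibrutinib 1, 2 and 3, 102 without asparaginase 2 and nearly the same without asparaginase 1, and 122, 93 and 73 without combination 1, 2 and 3.

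**Figure D5:**
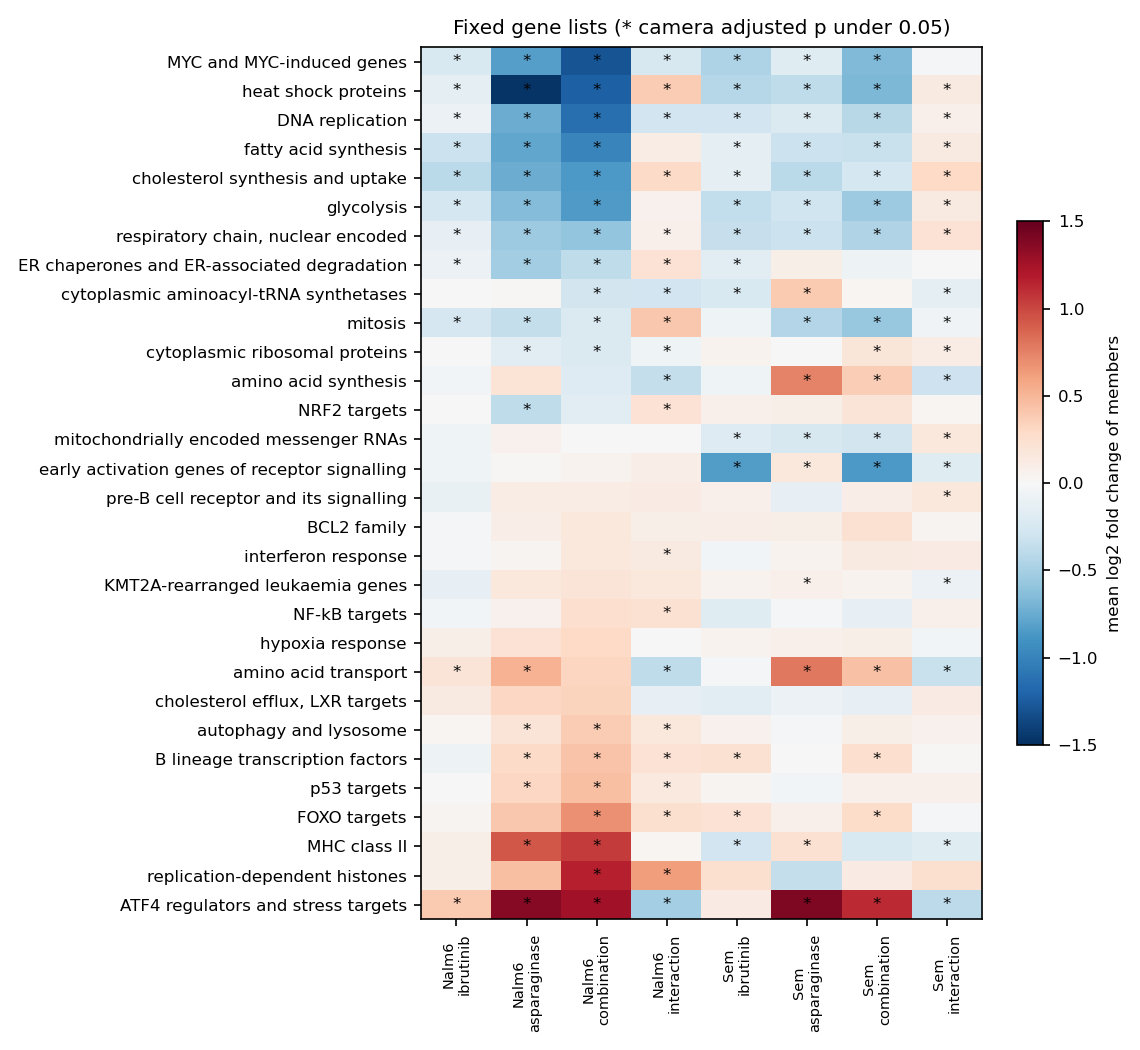
Mean log2 change of the tested members of 30 gene lists (rows) in 4 comparisons per line (columns), red higher and blue lower, with an asterisk at a camera adjusted p under 0.05. ATF4 genes are at 1.37 and 1.4 with asparaginase; another scaling turned the sign of amino acid synthesis with ibrutinib in both lines, of ER chaperones with ibrutinib, ribosomal proteins with asparaginase and both drugs and mitosis with both drugs in Nalm6, and of ribosomal, mitochondrial and DNA replication lists in the Sem interaction.

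Differences between the lines in each effect were tested in a joint fit of all libraries. Ibrutinib lowered DUSP6 in Sem relative to Nalm6 (Sem minus Nalm6 -2.81 ± 0.098, limma adjusted p = 6.7e-13), where its mean went from 17.7 ± 0.967 to 23.4 ± 1.01 FPKM, and early activation genes as a list (12 of 19 lower, 2 higher, mean -0.73, camera adjusted p = 9.91e-09). With asparaginase, the MYC list (32 of 33 higher, mean 0.64, camera adjusted p = 8.56e-19), DNA replication (30 of 35, mean 0.54), and heat shock proteins (14 of 16, 1 lower, mean 0.91) had fallen less in Sem. ER chaperones had fallen in Nalm6 and did not pass in Sem (line difference higher in 16 of 20, 2 lower, mean 0.61), and amino acid synthesis had risen in Sem and did not pass in Nalm6 (11 of 15 higher, 3 lower, mean 0.49). Under quantile normalization the rise of amino acid synthesis in Nalm6 did pass (mean 0.364, camera adjusted p = 0.00265). The ATF4 list did not differ by the test (8 higher, 7 lower, mean 0.03, camera adjusted p = 0.65), although ATF5 did (Sem minus Nalm6 2.2) and PPP1R15A lay the other way (-1.8). With both drugs IGLL1 differed by 3.07 ± 0.089 (adjusted p = 1.1e-14), having fallen to 248 ± 24.5 FPKM in Nalm6 and risen to 333 ± 11.3 in Sem. MHC class II genes were lower in Sem by this difference (9 of 10, mean -1.18). All these lists but the ATF4 one held with an estimated correlation. Of 15116 genes, 2062, 5059 and 6167 differed in the effects of ibrutinib, asparaginase and the combination (1142, 2681 and 3356 higher in Sem). After TPM rescaling 2127 were higher and 2879 lower for asparaginase, and 2771 and 3539 for the combination.

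Across 11741 genes tested in both lines, log2 changes correlated at r of 0.348 for ibrutinib, 0.534 for asparaginase, 0.59 for the combination and 0.154 for the interaction (Spearman 0.443, 0.566, 0.634 and 0.214). Genes are not independent replicates. These changes were not corrected for transcript length, on which library trends rose with asparaginase and with both drugs in both lines. With ibrutinib the trends rose in Sem and overlapped those of untreated libraries in Nalm6. How much this adds to the agreement was not tested. Ibrutinib raised 333 genes in both lines where independent calls would give 113, and lowered 658 in both where they would give 212. 104 of the 1095 called in both went opposite ways. For asparaginase 880 rose and 1460 fell in both (353 and 581 expected), and for the combination 2014 and 2433 (956 and 1100). In the interactions 21 lay above and 35 below the sum in both lines (2.7 and 2.28 expected).

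At baseline the lines differed in 9951 of 15116 genes (5142 higher in Sem). FLT3 (chromosome 13, 28003274 to 28100592, minus strand), a receptor kinase, averaged 400 ± 10.3 FPKM in Sem and 0.025 ± 0.0234 in Nalm6. DNTT, the polymerase that adds nucleotides at immunoglobulin joints, averaged 885 ± 67.1 in Nalm6 and 0.211 ± 0.145 in Sem. Of 16 KMT2A-rearranged leukaemia genes 15 were higher in Sem and 0 lower (mean log2 difference 3.3, camera adjusted p = 2.99e-11, held with an estimated correlation). HOXA9 averaged 28.7 ± 1.2 FPKM and was listed at 0 in untreated Nalm6. Ribosomal, mitosis, cholesterol and fatty acid genes were also higher and ER chaperones lower, with adjusted p of 0.133 to 0.597 with an estimated correlation. The call of the MYC list (7 higher, 21 of 33 lower, mean -0.21, adjusted p = 0.325 with an estimated correlation) was lost without Nalm6 untreated 3 (0.0566) or Sem untreated 2 (0.0672). MYC itself was lower in Sem (-1.11), as were TRIB3 (-2.74) and CHAC1 (-0.98). The kinase BTK (chromosome X, 101349447 to 101390796, minus strand) averaged 41.8 ± 1.04 FPKM in Nalm6 and 39.7 ± 0.715 in Sem, and ASNS (chromosome 7, 97852118 to 97872542, minus strand) 0.542 ± 0.0505 and 0.299 ± 0.118.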

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

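The tests on GC content, on the libraries that stood apart and on the untreated level of early activation genes were chosen after the results they concern were seen. The effects of each drug differed between Sem and Nalm6 by a test of the difference in the joint fit, and the values below are Sem minus Nalm6 on the log2 scale (list means over tested members, camera, and fitted changes of genes, limma). With ibrutinib, Sem lay lower for early activation genes (-0.73), MHC class II (-0.36), heat shock proteins (-0.32), the ATF4 list (-0.27), the MYC list (-0.23), tRNA synthetases (-0.22), the respiratory chain (-0.21), amino acid transport (-0.2), LXR targets (-0.2), DNA replication (-0.19), glycolysis (-0.1) and ER chaperones (-0.08). It lay higher for B lineage factors (0.3), cholesterol (0.24), mitosis (0.19), FOXO targets (0.18), the pre-B cell receptor list (0.18) and fatty acid synthesis (0.15). With an estimated correlation the calls of LXR targets, mitosis, the respiratory chain, ER chaperones, amino acid transport, glycolysis, FOXO targets, the pre-B cell receptor list and fatty acid synthesis were lost (camera adjusted p of 0.0674 to 0.228). Leaving out 1 library, the calls of ER chaperones (without Nalm6 ibrutinib 3, adjusted p = 0.0637, or Sem untreated 3, 0.0836), fatty acid synthesis (without Nalm6 untreated 1, 0.0615) and FOXO targets (without Nalm6 untreated 2, 0.0567, or Sem ibrutinib 3, 0.072) were lost. Among genes, EGR1 (-3.37), KCNK3 (-2.83), DUSP6 (-2.81), TRIB3 (-0.81), CHAC1 (-0.69), DDIT3 (-0.64) and BTK (-0.22) lay lower in Sem, and ASS1 (1.89, with uncertain decimal places), AC119396.1 (1.66) and RHOB (1.59) higher. The level of KCNK3 in Nalm6 is not given here, and a gene hardly expressed there could not fall.

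With asparaginase, Sem lay higher for heat shock proteins (0.91), the MYC list (0.64), ER chaperones (0.61), DNA replication (0.54), amino acid synthesis (0.49), NRF2 targets (0.45), fatty acid synthesis (0.39), tRNA synthetases (0.38), glycolysis (0.34), amino acid transport (0.31), cholesterol (0.3), the respiratory chain (0.22) and ribosomal proteins (0.16, negative under quantile normalization). It lay lower for histones (-0.7), MHC class II (-0.61), p53 targets (-0.36), LXR targets (-0.35), mitochondrial messenger RNAs (-0.3), B lineage factors (-0.26), autophagy genes (-0.23) and the pre-B cell receptor list (-0.22). With an estimated correlation the calls of LXR targets, autophagy genes, glycolysis, amino acid transport, B lineage factors, mitochondrial messenger RNAs, the respiratory chain, the pre-B cell receptor list and ribosomal proteins were lost (camera adjusted p of 0.0593 to 0.632). Leaving out 1 library, calls were lost for ribosomal proteins without Sem untreated 2 (0.139) and for LXR targets (0.0537) and the pre-B cell receptor list (0.0563) without Nalm6 untreated 2. ATF5 (2.2), UNC5B (2.13), TPBG (1.75), CHAC1 (1.5), MYC (0.6), ASNS (0.28) and ATF4 (0.18) lay higher in Sem, and YPEL3 (-2.21), LGALS1 (-2.17), ENPP2 (-2.13), DDIT3 (-0.99) and BTK (-0.15) lower. The calls of ASNS, ATF4 and BTK were lost in 7, 6 and 5 of 12 fits without 1 library (adjusted p up to 0.109, 0.115 and 0.085).

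With both drugs, Sem lay higher for DNA replication (0.72), the MYC list (0.63), fatty acid synthesis (0.58), cholesterol (0.57), amino acid synthesis (0.54), heat shock proteins (0.38), ribosomal proteins (0.38), NRF2 targets (0.34), ER chaperones (0.31), tRNA synthetases (0.3) and glycolysis (0.29). It lay lower for MHC class II (-1.18), early activation genes (-0.86), histones (-0.72), p53 targets (-0.4), FOXO targets (-0.36), mitosis (-0.35), autophagy genes (-0.29), mitochondrial messenger RNAs (-0.27) and hypoxia genes (-0.21). With an estimated correlation the calls of autophagy genes, mitosis, NRF2 targets, heat shock proteins, FOXO targets, glycolysis, ribosomal proteins, hypoxia genes and mitochondrial messenger RNAs were lost (camera adjusted p of 0.0706 to 0.383). The hypoxia call was lost in 4 and the mitochondrial call in 6 of 12 fits without 1 library (adjusted p up to 0.0794 and 0.104). IGLL1 (3.07), PLD4 (2.6), MT1G (2.41), MYC (1.33), CHAC1 (1.02), ASNS (0.28) and ATF4 (0.19, but -0.023 under quantile normalization) lay higher, and EGR1 (-3.55), DUSP6 (-3.46), TSPAN8 (-3.36), DDIT3 (-1.01), TRIB3 (-0.78) and BTK (-0.38) lower. The calls of ASNS and ATF4 were lost in 8 and 5 of 12 such fits (up to 0.0987 and 0.0805).

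Other splits of the samples were fitted with the same model. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05: in each of these comparisons 1 of 10 splits, the real one, gave as many genes, against a highest other count of 0 or 1 (for example 1650 against 0 for ibrutinib in Nalm6 and 5563 against 1 in Sem). For the interactions, 3 of 100 splits drawn gave as many genes, the real one included, in Nalm6 (736, highest other 7773) and in Sem (207, highest other 2351), but this count does not decide on chance. The other splits drawn mixed libraries of different treatments, so the drug effects entered their contrast or their spread. The highest called about 10 times the real count, which points to such a structure of the samples. For the line differences in the effects of ibrutinib, asparaginase and the combination, 6, 11 and 7 of 100 splits gave as many genes. The real counts were 2062, 5059 and 6167, and the highest others 5853, 8006 and 7363. This count does not decide on chance either. All 5, 10 and 6 others as large kept or exchanged whole groups of at least 1 line. They still set treated against untreated cells of that line, so drug effects entered their contrast. Splits that mixed the groups of both lines called at most 2, 2 and 1 genes.

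The first pattern weighed was the set of genes called in Nalm6 for ibrutinib (1650) and for the interaction (736), since Nalm6 libraries differed in their trend on GC content and 3 of them stood apart. After the GC and length correction 93% of the ibrutinib calls and 97.4% of the interaction calls were kept. Without the libraries that stood apart, 99.1% and 98.6% kept their direction and at least 0.75 of their log2 change. For ibrutinib only untreated 2 was left out of the compared libraries, so a kept size was likely beforehand. Of the calls themselves, 1540 of 1650 and 638 of 736 were kept, among 3325 and 1586 genes then called. Since most calls were kept, neither trend nor those libraries can be their whole cause. A drug effect stays a hypothesis. A batch shared by libraries of a group, which the labels do not give, stays open.

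The second pattern was the ATF4 list below the sum of the single drugs in both lines. Of median-ratio and quantile scaling, the one nearer 0 gave a list mean of -0.5 in Nalm6 and -0.38 in Sem, and the GC and length correction gave -0.51 and -0.4. All passed the camera threshold. Median-ratio scaling could hardly move these means, since the median interaction of all genes was already 0.0014 in Nalm6 and 0.0037 in Sem. With quantile scaling and the GC and length correction the list still passed, so neither the scaling of libraries nor GC content is the whole cause. In Nalm6 ibrutinib alone raised the list by 0.397, and adding it to asparaginase gave -0.11 (camera adjusted p = 0.0945 with an estimated correlation), so much of the shortfall there is a rise with ibrutinib that did not add to that with asparaginase. In Sem that addition gave -0.28 (0.206 with an estimated correlation). With the preset correlation camera called the list lower for this addition in both lines. Since these calls were lost with an estimated correlation, whether ibrutinib dampens the response stays open in both lines. A limit on how far these genes can rise, a different time course with both drugs, and a loss of dying cells were not tested and stay open.

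The third pattern was the fall of early activation genes with ibrutinib in Sem. The first form of the test by level asked that no member at 5 FPKM or more in untreated Nalm6 be called lower there, and SPRY2 was (-0.43, limma adjusted p = 0.0016). A second form counted called line differences among members called lower in Sem, a choice that built in its outcome, and was dropped. The last form took all 10 list members at that level, whatever their call in Sem. Their mean line difference was -0.6 (SE over members 0.29, camera p = 8.3e-06, and 0.0029 with an estimated correlation), with 6 called lower and 0 higher in Sem, so low levels in Nalm6 are not the whole cause. FOS, FOSL1 and SPRY4 were too low in Nalm6 to be tested there, and for them this stays open. With the GC and length correction the list mean of the line difference was -0.74, past the camera threshold. A stronger dependence of Sem on a kinase that ibrutinib inhibits may underlie the pattern, as a hypothesis, for which neither kinase activity nor other inhibitors were measured.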

How the results depend on the processing

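The analyses without the libraries that stood apart, with the GC and length correction and without genes of an uncertain restored value were chosen after the data were seen. The set of single genes followed was narrowed to the genes picked by the rule, the 7 always given and the called ones among up to 4 members picked per called list after the first reversed results were seen. Each result was counted once per setting, and many settings share libraries. For 1207 single-gene results, 25479 counts kept direction and side of the threshold, 480 lost and 54 gained their call and 35 reversed. Many of these genes were picked for large changes in these data, which favours stability. For 249 called list results, 5590 counts kept both, 356 lost their call and 9 reversed. The main tests of the ATF4 and amino acid synthesis lists, given below, were counted apart: 5 lost and 5 gained their call and 5 reversed. Where no cause is given below, the cause was not tested.

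Counts moved by more than 1.5 times for 4 comparisons. Ibrutinib in Nalm6 (1650) gave 1056 with no filter (more genes tested), 857 with quantile normalization, 2507 with both lines in 1 fit (more libraries and more genes tested), 3325 without the libraries that stood apart and 2672 with the GC and length correction, and 703 (without untreated 3) to 1524 (without untreated 2) leaving out 1 library. The Nalm6 interaction (736) gave 1364 with both lines in 1 fit, 1586 without the libraries that stood apart, 1647 with the correction, and 430 (without ibrutinib 2) to 966 (without combination 1). The Sem interaction (207) gave 136 with no filter, 355 with TPM rescaling, 405 for protein-coding genes, 533 with voom weights, and 73 (without combination 3) to 369 (without untreated 2). Adding asparaginase to ibrutinib in Sem (1624) gave 1044 (without combination 2) to 1181 (without ibrutinib 1). The other 12 counts stayed within 1.5 times under each setting.

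The mean of amino acid synthesis with ibrutinib turned positive with TPM rescaling (0.035 in Nalm6, 0.021 in Sem), quantile normalization (0.016, where it was called higher at a camera adjusted p = 0.0265, and 0.01) and, in Nalm6, without genes of an uncertain restored value (0.092, since these include ASS1). It passed with asparaginase in Nalm6 by fry (0.205) and quantile normalization (0.364) and with both drugs by fry (-0.192). With an estimated correlation it did not pass with both drugs in Sem (0.371, adjusted p = 0.296) or for ibrutinib added to asparaginase there (-0.374, 0.0786), nor did the ATF4 list for that addition in Sem (-0.275, 0.206) and Nalm6 (-0.11, 0.0945, and 0.0533 for protein-coding genes at the same mean). The ATF4 list passed with ibrutinib in Sem by fry (0.123) and TPM rescaling (0.227). All other list tests gave 243 calls, 94 with an estimated correlation and 341 by fry. Under quantile normalization means turned for ER chaperones (ibrutinib in Nalm6, 0.002), ribosomal proteins (Nalm6 asparaginase 0.154 and combination 0.101, both called higher, at 0.00049 and 0.0498, combination against ibrutinib 0.013, Sem interaction -0.004, line difference for asparaginase -0.04), mitosis (Nalm6 combination 0.007) and mitochondrial messenger RNAs (Sem interaction -0.017), and with TPM rescaling for DNA replication (Sem interaction -0.005).

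Single genes also reversed. With quantile normalization these were ASNS (Nalm6 ibrutinib, -0.027), BTK (Nalm6 interaction -0.008, Sem ibrutinib 0.065, asparaginase 0.001, combination 0.041, combination against asparaginase 0.041, interaction -0.025), MYC (Sem combination against ibrutinib, 0.018), FADS2 (Sem ibrutinib, 0.034) and ATF4 (line difference for the combination -0.023, baseline -0.144, called in this other direction at a limma adjusted p = 0.00247). With TPM rescaling they were BTK (Sem ibrutinib 0.004, interaction -0.04), MYC (Sem combination against ibrutinib, 0.001) and ATF4 (baseline, -0.015). ATF4 turned with median-ratio scaling (Nalm6 combination against ibrutinib, -0.015), without the libraries that stood apart (Sem ibrutinib, -0.015) and with the GC correction (baseline, -0.003). TRIB3 in the line difference for asparaginase gave 0.287 with a pseudocount of 0.1, 0.139 with TPM rescaling, 0.336 with voom weights and 0.043 without the libraries that stood apart, and ABCA1 in that for ibrutinib 0.67 with voom weights. Leaving out 1 library gave -0.008 to 0.015 (ATF4, Nalm6 combination against ibrutinib), -0.004 to 0.057 (ATF4, Sem ibrutinib), -0.011 to 0.004 (MYC, Sem combination against ibrutinib), -0.01 to 0.107 (ASNS, line difference for ibrutinib), -0.127 to 0.064 (TRIB3, line difference for asparaginase) and -0.008 to 0.051 (ATF4, baseline).

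Library numbers were not treated as pairs. Residuals of libraries of the same number correlated at -0.174 to 0.371 in Nalm6 (median 0.014) and -0.04 to 0.11 in Sem (median 0.041), and 7 and 9 of 12 libraries were closest to one of their own number. Between libraries of other numbers and groups the medians were 0 in Nalm6 and -0.022 in Sem. A structure by number is therefore not excluded, and the Sem values lean towards one. With the number as a block 1484 genes were called for ibrutinib in Nalm6 and 5805 in Sem. Depth limits genes of low level: ASNS in untreated libraries rested on 38.3 reads per library in Nalm6 and 21.7 in Sem, and FOS in untreated Nalm6 on 6.33.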

Other observations

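Beyond the picked genes, 4 genes of B cells are given here, chosen after their values were seen; they stand for no list, and the line difference of the pre-B cell receptor list did not pass with an estimated correlation (camera adjusted p = 0.228 for ibrutinib and 0.384 for asparaginase). The interleukin 7 receptor gene IL7R averaged 75 FPKM in untreated Nalm6 and 42.8 with ibrutinib, and 38.1 and 48.1 in Sem (line difference 1.13, limma adjusted p = 5.8e-09). The survival gene BCL2 averaged 5.57 and 3.61 in Nalm6 and 29.6 and 39.1 in Sem (line difference 0.9, limma adjusted p = 7.8e-09). With asparaginase, CD79A, a chain of the B cell receptor, rose in Nalm6 (1.66) and did not pass in Sem (0.1), with a line difference of -1.56 (limma adjusted p = 2.1e-07), and CD79B rose by 0.53 in Nalm6 and fell by 0.53 in Sem (line difference -1.06).

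Means of TFRC and LDHA, both of the MYC list, were lower with each drug in both lines. TFRC averaged 69.9 FPKM in untreated Nalm6, 53.8 with ibrutinib, 19.5 with asparaginase and 15.5 with both, and in Sem 54.3, 29.6, 30.9 and 19.2. LDHA averaged 106, 72, 34.4 and 25 in Nalm6 and 158, 88.3, 102 and 63 in Sem.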
